A study of Arabidopsis thaliana with 6 samples.

How the data were processed

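Whole 7-day-old Arabidopsis thaliana seedlings of the Col-0 accession were profiled on expression arrays: 3 wild type samples and 3 samples of cdkf;1-2, a T-DNA insertion mutant. The labels call the samples biological replicates and do not say whether they were grown or processed together. They give the age once as days after germination and once as days after sowing. Per the labels' protocols, seedlings grew at 22 °C on solid medium with 0.5% sucrose under 8 h of light and 16 h of dark, and were collected 4 h after the lights came on. Total RNA was extracted on columns with a DNase step, and biotin-labelled cRNA was made by linear amplification from 1 µg of it.

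The table holds 22810 probe sets, each a group of short oligonucleotides that together measure a transcript. The authors deposited one linear intensity per probe set and sample. GCOS, the array maker's operating software, is named per the submitters' processing notes; its version and settings, and any scaling between arrays, are not given in the sources used here. The deposited intensities did not share a common scale. The median signal was 93.8, 104 and 85.0 in wild type replicates 1 to 3 and 64.1, 89.1 and 114 in mutant replicates 1 to 3. The design written before the data were examined took the values as already normalized. After the medians were seen, and before any test between genotypes, the main setting was changed to quantile normalization, which had been listed as an alternative, and the fit on the deposited values became an alternative. No detection calls were used here, so which probe sets lay above background is not stated. The number of arrays limits the precision of every value.

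Signals were quantile-normalized over all probe sets, 16 was added, and log2 was taken. A fold change is on this log2(signal + 16) scale, which understates the change of dim transcripts. The 64 control probe sets were then left out and the other 22746 were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, 4 residual degrees of freedom, two-sided). P-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05 and no filter on dim probe sets. Errors of differences are limma's standard errors (SE).

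Genes were named from the array's annotation, with symbols updated through the RefSeq gene table of the assembly TAIR10.1 for 13436 probe sets. In all, 13513 probe sets had 1 gene, 503 had several and were not named, and 8730 were not listed and are unnamed here. The build behind the probe sets is not given in the sources used here, so no coordinates are printed. The named probe sets covered 13356 genes, and the one with the highest mean signal stood for a gene. No probe set was named for CDKF;1, so its transcript level was not analysed here.

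The text names the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap and whose higher group mean lay above the median of all probe sets. It also names up to 4 members past the threshold of each gene list it leads with, largest change first, and members given as values for not passing. This rule, 24 gene lists and a set of family keywords were fixed before the data were examined. The keywords were meant for gene descriptions but were matched to symbols and synonyms. A keyword list therefore holds only the genes so named, not the whole family. The peroxidase and lipid transfer protein keywords found 0 genes. Only 65 of the 450 members of the 24 lists had a named probe set. A further 34 lists, made from the symbols in the annotation, were therefore added before any test. Lists with at least 5 measured genes, 43 in all, were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and limma's fry alongside. Another 25 lists with fewer genes were described and not tested. Control probe sets were compared by an exact permutation test of 3 samples against 3, whose smallest two-sided p is 0.1.

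The alternatives were the deposited values, centring on each array's median, scaling to a common 2% trimmed mean, scaling on the hybridisation spikes, leaving out the 40% or 60% dimmest probe sets, a trended and robust prior variance, pseudocounts of 1 and 64, array weights, the replicate number as a block, each sample left out, and the mean of a gene's probe sets. The trimmed-mean and spike scalings were added after the columns were seen.

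The fit was tested on simulated data for this comparison, with 22746 probe sets and 200 changed ones drawn from those brighter than the median. It recovered 6 of 67 changes of 1.5-fold, 55 of 67 of 2-fold and 66 of 66 of 4-fold. It made 9 false calls among 136, and limma made 0 with none changed. The real fit called 3267 probe sets, so its cut on the unadjusted p was looser. The simulated shares are therefore not the recovery of such changes in the real data. A simulated list of 20 genes shifted by 0.5 was called, and 0 of 42 unshifted lists were. The simulated genes were drawn independently, so this says nothing on false calls of lists whose members correlate. In the other 9 splits of the 6 real samples camera called 0 to 7 lists and limma called 0 probe sets. Each of these splits mixes the genotypes unequally. Part of the genotype difference stays in the contrast, so these list calls are not a count of false calls. Gene lists and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.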

Results

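Transcript levels were measured in whole seedlings of 2 genotypes, 3 samples each: wild type Arabidopsis thaliana (Col-0) and the cdkf;1-2 insertion mutant. CDKF;1 is a plant-specific cyclin-dependent kinase that activates other kinases of this family, and the study names it as a kinase of Ser-7 in the carboxy-terminal repeats of RNA polymerase II. The 1 comparison in the design, mutant against wild type, asks which transcripts differ in young seedlings that carry the mutation. Quantile-normalized signals correlated at r = 0.982 to 0.987 between wild type samples, 0.973 to 0.987 between mutant samples and 0.952 to 0.960 between genotypes, across probe sets, which are not independent replicates. The transcript of CDKF;1 itself was not analysed here, so it gives no check of the genotype labels.

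In cdkf;1-2 seedlings the gene with the largest rise among those named by the rule was AT2G43620, of the chitinase family, at 37.4-fold (log2 difference 5.23, SE 0.21, n = 3 per group, limma adjusted p = 7.6e-05). ICL, the isocitrate lyase of the glyoxylate cycle through which oilseed seedlings use stored fat, rose 10.3-fold (log2 3.36, SE 0.25, limma adjusted p = 0.000526), and the other measured gene of the seed storage and reserve list, AT1G03890, did not pass (log2 -0.23, SE 0.29). Camera called upward shifts of a list of 9 expansins and xyloglucan-modifying enzymes (6 rose), of 15 defensins and thionins (7 rose) and of 14 phenylpropanoid, flavonoid and anthocyanin enzymes (6 rose, 1 fell). AT1G62510, of the lipid-transfer protein type, fell 9.58-fold (log2 -3.26, SE 0.30, limma adjusted p = 0.00101). For 13 genes of tetrapyrrole and chlorophyll synthesis, of which 4 fell, the downward call was lost under each of the 4 other scalings of the arrays (adjusted p = 0.184, 0.123, 0.0722 and 0.347), where the list median of -0.39 became -0.28, -0.16, -0.31 and, under hybridisation spike scaling, 0.05. These calls used camera's preset correlation, and 0 of them held when the correlation was estimated (smallest adjusted p = 0.374 with an estimated correlation). For expansins and defensins the estimates, 0.08 and 0.208, lay above the preset of 0.01. For phenylpropanoid enzymes and tetrapyrrole synthesis they lay below it, at -0.038 and -0.013. A higher correlation among members therefore does not explain the loss of these last calls, and what else differs between the forms of the test was not examined. With the preset, camera also called up to 7 lists when the samples were split into mixed groups. Such splits keep part of the genotype difference, so they give no rate of false calls.

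Other genes with large rises included AT2G04050, a member of the MATE efflux carrier family, at 14.2-fold (log2 3.83, SE 0.14), and AT1G65500 at 13.2-fold (log2 3.72, SE 0.17). AT5G38910, a germin-like gene, rose 9.57-fold, and the peroxidase genes AT4G36430 and AT1G49570 rose 9.43-fold and 6.85-fold. AT3G18280, of the lipid-transfer protein type, rose 7.83-fold, AT3G16330 rose 7.49-fold, and AT1G53080, of the legume lectin type, rose 7.35-fold. The tau-class glutathione S-transferase gene GSTU20 rose 6.39-fold (log2 2.68, SE 0.23), from normalized signals of 266, 330 and 507 in wild type to 2159, 2301 and 2624 in the mutant. The defensin gene PDF2.1 rose 6.07-fold (log2 2.60, SE 0.39, limma adjusted p = 0.00578). Wild type signals of AT3G16330, AT1G53080 and PDF2.1 were all at or below 10.5, so their fold changes depend on the added 16.

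Among the falls, AT1G70820 dropped 8.60-fold (log2 -3.10, SE 0.25), and AT3G49960, a class III peroxidase gene, dropped 6.30-fold (log2 -2.66, SE 0.22). The neighbouring jacalin-type lectin genes AT1G52060 and AT1G52070 fell (log2 -2.47, SE 0.17, and log2 -2.07, SE 0.24). AT2G47890, which encodes a B-box zinc finger protein, fell 5.52-fold (log2 -2.47, SE 0.33). AT2G03310 fell 5.55-fold (limma adjusted p = 0.0131), AT1G13650 fell 5.31-fold and AT2G23840 fell 5.03-fold. AT5G42250, an alcohol dehydrogenase-like gene, fell 4.62-fold, and AT4G16880 fell 4.51-fold. ATSPS4F, a sucrose-phosphate synthase gene, fell 4.32-fold (log2 -2.11, SE 0.20, limma adjusted p = 0.00112). The call of AT2G03310 ended without wild type replicate 2 (log2 -2.35, adjusted p = 0.0588), without wild type replicate 3 (log2 -2.40, adjusted p = 0.0537) and with a pseudocount of 1 (log2 -3.52, adjusted p = 0.0559). That of PDF2.1 ended on the deposited signals (log2 2.59, adjusted p = 0.0529). Mutant signals of AT3G49960 were at or below 10.8 and those of AT1G13650 at or below 16.7, so these falls depend on the added constant too. With a pseudocount of 1 in place of 16 the fold of 9 of the 24 genes moved by over 1.5 times, and with 64 that of 16. Among the falls, AT3G49960 went to log2 -4.49 and -1.39, AT1G13650 to -4.25 and -1.23, AT1G70820 to -4.22 and -1.95, AT2G03310 to -3.52 and -1.47 and AT2G47890 to -3.18 and -1.56. Among the rises, AT1G53080 went to 4.72 and 1.52, AT3G16330 to 4.54 and 1.58, PDF2.1 to 4.11 and 1.41 and AT5G38910 to 4.08 and 2.18. Only with 64 did AT2G43620 (log2 4.35), AT2G04050, AT1G65500, AT4G36430, AT1G49570, AT2G23840 and AT4G16880 move this far. Probe sets without a single gene name were ranked under the same conditions. Their 2 largest rises were log2 3.69 and 3.36, and their 2 largest falls log2 -3.46 and -3.43.

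**Figure D1:**
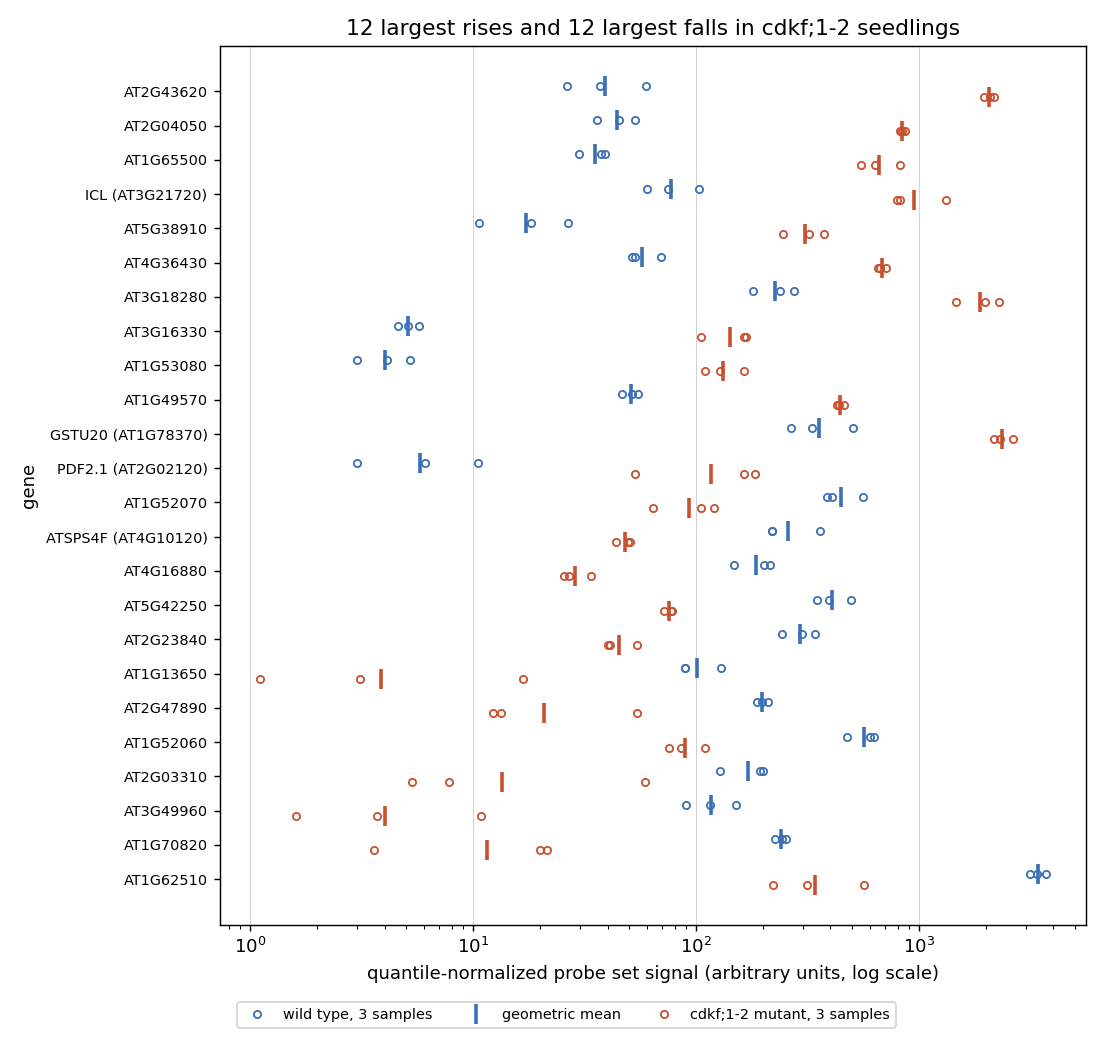
Normalized probe set signal (arbitrary units, log axis) of the 12 genes with the largest rise and the 12 with the largest fall; circles are the 3 wild type and 3 cdkf;1-2 samples, and vertical bars are geometric means. The genes were chosen to have groups that do not overlap, and the mutant samples of AT2G43620 lie between 1958 and 2154 against 26.4 to 59.8 in wild type.

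Over all 22746 probe sets, limma called 3267, of which 1579 were higher and 1688 lower in the mutant. Of these, 1015 differed at least 2-fold, 595 higher and 420 lower. Counted as genes, 1748 of 13356 passed, 878 higher and 870 lower. The groups did not overlap for 7713 probe sets, 33.9% of those tested against 10% by chance, and for all 1015 of the 2-fold calls. On the deposited signals without normalization limma called 328 probe sets (150 higher, 178 lower), and 45.7% of its 2-fold calls were higher against 58.6% after quantile normalization. With arrays scaled on the hybridisation spikes, which shifts the median of all probe sets by 0.18, 1624 probe sets were called and 80.4% of them were higher, against 48.3%. Leaving out any of wild type replicates 1 to 3, mutant replicate 2 or mutant replicate 3 left 1837, 1496, 2019, 1873 or 1865 calls, and leaving out mutant replicate 1 gave 4107.

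Some array controls differed between the genotypes as well. The 25S ribosomal RNA control, relative to the median of all probe sets of its array, was 2.05-fold higher in the mutant (log2 1.03; SD of 0.13 in wild type and 0.19 in the mutant, n = 3 each, exact permutation p = 0.1, the smallest possible). The 5S ribosomal RNA control was 1.09-fold higher, with overlapping groups (SD of 0.13 in wild type and 0.56 in the mutant, exact permutation p = 0.8 with n = 3 per group). The 4 bacterial poly(A) control transcripts together were 1.64-fold higher on the same basis (log2 0.71, exact permutation p = 0.1 with n = 3 per group). The ratio of 3' to 5' probe set signals, a measure of RNA integrity and of labelling, moved from 2.29 ± 0.22 to 2.81 ± 0.15 for actin (SD, n = 3) and from 0.914 ± 0.040 to 1.04 ± 0.038 for GAPDH. For ubiquitin it moved the other way, from 1.66 ± 0.073 to 1.43 ± 0.081 (SD, n = 3). In each of these 3 ratios the groups did not overlap (exact permutation p = 0.1 with n = 3 per group).

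**Figure D2:**
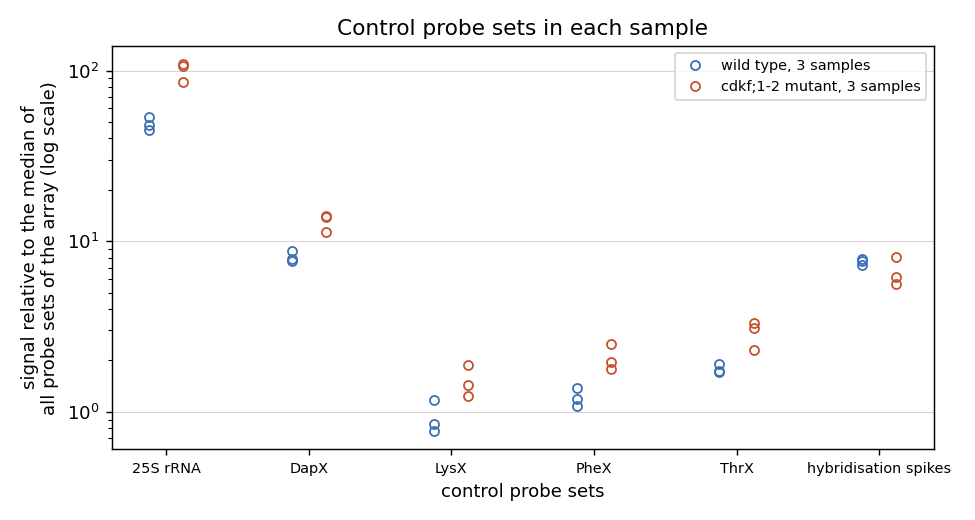
Signal of control probe sets relative to the median of all probe sets of the same array (log axis), each circle 1 of the 3 wild type or 3 cdkf;1-2 samples. The 25S rRNA ratios are 45.0 to 53.7 in wild type and 86.0 to 109 in the mutant, the 4 poly(A) control transcripts (DapX, LysX, PheX, ThrX) are also separated, and the hybridisation spikes overlap.

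Cell wall genes were the list with the smallest p. Of 9 measured expansins and xyloglucan endotransglucosylase/hydrolases, proteins that loosen and remodel the wall, 6 rose, 0 fell and 3 did not pass (limma). At an unadjusted threshold of 0.05, 7 were higher and 0 lower. Adjusted over the list alone, 7 rose. XTH19 rose 4.96-fold (log2 2.31, SE 0.12, limma adjusted p = 0.000178), EXPA4 rose 2.96-fold (log2 1.57, SE 0.14), and EXPB3 and XTH18 rose 2.00-fold and 1.94-fold. The 3 that did not pass were EXPB1 (log2 0.39), XTH20 (log2 0.23) and EXPA8 (log2 -0.27). Camera gave an adjusted p = 0.000318, and adjusted p = 0.374 with an estimated correlation. In the wider list of 28 expansin and xyloglucan enzyme genes, which holds all 9, 10 rose and 3 fell (camera adjusted p = 0.0271, and adjusted p = 0.546 with an estimated correlation). This call was also lost under 6 of 18 other settings (camera adjusted p up to 0.144). EXLB1 rose 3.11-fold and EXPA20 rose 2.32-fold. The 3 that fell, named after their values were seen, were XTH26 (log2 -1.03, SE 0.21), EXGT-A3 (log2 -0.90, SE 0.13) and EXPA18 (log2 -0.73, SE 0.17). EXPA18 and EXPA7 are the 2 measured genes of the root and root hair list. EXPA7 did not pass over all probe sets (log2 -1.42, SE 0.41, limma adjusted p = 0.062), while both fell adjusted over the list alone, and 4 genes fell adjusted over the wider expansin list.

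Of 15 measured defensins and thionins, small antimicrobial peptides, 7 rose, 0 fell and 8 did not pass (limma, 7 higher and 0 lower at an unadjusted threshold of 0.05), and camera called the list (adjusted p = 0.000821; adjusted p = 0.525 with an estimated correlation). Besides PDF2.1, LCR69 rose 2.85-fold (log2 1.51, SE 0.16), LCR68 rose 2.79-fold (log2 1.48, SE 0.21) and THI2.2 rose 2.19-fold (log2 1.13, SE 0.16). Of the 3 measured genes of the jasmonate and wounding list, all also in this list, PDF1.2b rose 1.69-fold (log2 0.76, SE 0.14, limma adjusted p = 0.0122). PDF1.2 and THI2.1 did not pass (log2 0.28 and 0.43, limma adjusted p = 0.462 and 0.251), and adjusted over the list alone 1 of the 3 rose. In a list of genes that respond to elicitors and wounding, 5 of 14 rose and 0 fell (limma, with 6 higher and 0 lower at an unadjusted threshold of 0.05). Camera gave an adjusted p = 0.0206, and adjusted p = 0.525 with an estimated correlation. The call was also lost under 5 of 17 other settings (camera adjusted p up to 0.0749). The rises were led by the zinc finger gene STZ, 2.23-fold (log2 1.16, SE 0.14), WRKY53, 1.87-fold, the transcription factor gene ORA47, 1.75-fold, and the receptor-associated kinase gene BIK1, 1.44-fold.

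Of 14 measured phenylpropanoid, flavonoid and anthocyanin enzymes 6 rose, 1 fell and 7 did not pass (camera adjusted p = 0.00309; adjusted p = 0.374 with an estimated correlation). DFR, dihydroflavonol reductase, rose 3.28-fold (log2 1.71, SE 0.19, limma adjusted p = 0.00229). The flavonoid glycosyltransferase gene UGT78D2 rose 1.98-fold and UF3GT, which adds xylose to anthocyanins, rose 1.93-fold (log2 0.94, SE 0.17). UGT72E3, which glucosylates precursors of lignin, fell by 0.92 on the log2 scale (SE 0.23, limma adjusted p = 0.0406), and 0 genes of the list fell without mutant replicate 1. All 4 measured genes of the flavonoid and anthocyanin list fixed in advance rose, also adjusted over the list alone: DFR, AT4G14090, UGT78D2 and UF3GT. This list was too short to be tested. Of 45 genes found by the UDP-glycosyltransferase keyword 16 rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell. Camera gave an adjusted p = 0.00813, and adjusted p = 0.525 with an estimated correlation. UGT73C1, UGT71B1, UGT76E12 and UGT76C2 rose 2.77-fold, 2.52-fold, 2.52-fold and 2.44-fold. The 2 that fell, named after their values were seen, were UGT71C1 (log2 -0.71) and UGT76E11 (log2 -0.57), and 1 fell without mutant replicate 1. The list shares 5 genes with the phenylpropanoid list. In the same mutant samples that gave these upward shifts, the 25S rRNA control was 2.05-fold and the poly(A) controls 1.64-fold above wild type.

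Of 13 measured genes of tetrapyrrole and chlorophyll synthesis 4 fell and 0 rose (limma, 7 lower and 0 higher at an unadjusted threshold of 0.05, camera adjusted p = 0.00965; adjusted p = 0.374 with an estimated correlation). HEME2, a uroporphyrinogen decarboxylase, fell by 0.91 on the log2 scale (SE 0.11, limma adjusted p = 0.00284), and CHLI2, a magnesium chelatase subunit, fell by 0.86 (SE 0.12). CHLM, the next methyltransferase of the chlorophyll branch, fell by 0.54 (SE 0.14), with a difference of 0.01 once arrays were scaled on the hybridisation spikes, and HEME1 fell by 0.51 (SE 0.13). Of 8 measured nuclear photosynthesis genes 2 fell and 0 rose, and 3 fell adjusted over the list alone (limma, 3 lower and 0 higher at an unadjusted threshold of 0.05, camera adjusted p = 0.0206; adjusted p = 0.525 with an estimated correlation). The call was lost under each of the 4 other scalings (adjusted p = 0.480, 0.412, 0.206 and 0.703), without the 40% or 60% dimmest probe sets and without mutant replicate 1. The list median stayed negative on the deposited signals (-0.23), with median centring (-0.11) and with the trimmed mean (-0.26). PRK, the phosphoribulokinase of the Calvin cycle, fell by 0.72 (SE 0.12), and PSAN, a photosystem I subunit, fell by 0.59 (SE 0.12). Rubisco activase RCA (log2 -0.17) and the antenna gene LHCB4.1 (log2 -0.15) did not pass. The list medians of log2 -0.39 for chlorophyll synthesis and -0.31 for photosynthesis turned to 0.05 and 0.10 under hybridisation spike scaling, and relative to the shift of all probe sets there they were -0.13 and -0.07. In these samples the 3' to 5' ratios of actin and GAPDH were higher and that of ubiquitin lower than in wild type, with the values above.

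**Figure D3:**
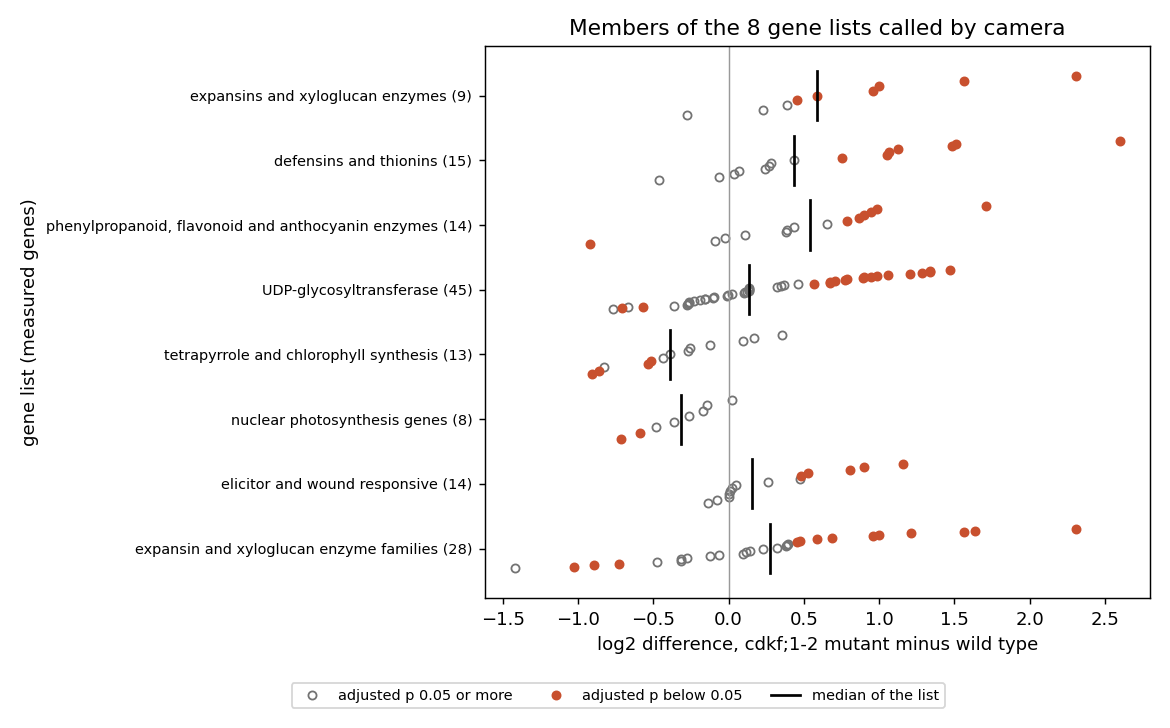
Log2 difference (cdkf;1-2 mutant minus wild type) of each measured gene, 1 circle per gene, in the 8 lists called by camera with the preset correlation; filled circles passed limma's threshold and vertical bars are list medians. Medians run from -0.39 for tetrapyrrole and chlorophyll synthesis, which turned to 0.05 under hybridisation spike scaling, as photosynthesis did from -0.31 to 0.10, to 0.58 for expansins and xyloglucan enzymes.

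Lists of the transcription machinery and of RNA processing, made from the symbols in the annotation, were not called. Of the lists fixed in advance, that of RNA polymerase II carboxy-terminal kinases and phosphatases had 0 of 13 genes measured, and pre-mRNA splicing 3 of 22. Of 17 nuclear RNA polymerase and Mediator subunit genes 1 rose and 0 fell (limma, 3 higher and 1 lower at an unadjusted threshold of 0.05, camera adjusted p = 0.321), and without mutant replicate 1 there were 5 that rose. The one that rose was NRPD7, at 2.02-fold (log2 1.02, SE 0.18, limma adjusted p = 0.0101). Of 27 genes of mRNA processing, export and decay 0 passed (limma, 1 higher and 1 lower at an unadjusted threshold of 0.05, camera adjusted p = 0.599), against 1 that rose without mutant replicate 1. The related splicing factor genes PRP39 and PRP39-2, named after their values were seen, had log2 differences of 0.35 (SE 0.13) and -0.42 (SE 0.16). Of 4 measured small RNA pathway genes 0 passed, and 1 fell adjusted over the list alone (limma, 0 higher and 1 lower at an unadjusted threshold of 0.05). Among them, named after their values were seen, AGO7, the Argonaute of the trans-acting siRNA pathway, had a log2 difference of -0.91 (SE 0.25, limma adjusted p = 0.0528) and SE, which encodes a microRNA processing factor, 0.18 (SE 0.20).

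A list of cell division genes, also made from the symbols in the annotation, was not called either. Of the genes fixed in advance, 2 of 18 for mitosis and cytokinesis and 2 of 16 for DNA replication were measured. Of 20 measured genes of cell division and DNA replication 0 passed (limma, 3 higher and 1 lower at an unadjusted threshold of 0.05, camera adjusted p = 0.791), against 1 that rose without mutant replicate 1. Named after their values were seen, the kinase gene AUR1 had a log2 difference of 0.38 (SE 0.12, limma adjusted p = 0.0705) and the MCM7 gene PRL -0.48 (SE 0.18, limma adjusted p = 0.12). The one measured gene of the inhibitors of cyclin-dependent kinases, SIM, rose (SE 0.23, limma adjusted p = 0.0141), from a mean log2 signal of 8.27 to 9.47. Of 12 genes found by the glutathione S-transferase keyword 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.173). GSTU25 was up 1.92-fold and GSTU26 down by 0.87 on the log2 scale. Of 24 genes found by the cytochrome P450 keyword 6 fell and 1 rose, and adjusted over the list alone 6 fell and 2 rose (camera adjusted p = 0.192). CYP71B35 fell by 1.48, CYP71B37 by 1.38 and CYP71B26 by 1.15 on the log2 scale, and CYP71B23, named after its value was seen, rose 1.86-fold.

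The calls of the shorter expansin list, of defensins and thionins and of phenylpropanoid enzymes held under all 18 alternatives other than the estimated correlation. Those of the other 5 lists ended under between 1 and 7 of them, most often for nuclear photosynthesis genes. Lists not called gained a call under some alternatives: cytochrome P450 genes with spike scaling (adjusted p = 0.0192) and glutathione S-transferases without the 60% dimmest probe sets (adjusted p = 0.0270). Of 69 plastid-encoded genes 3 rose and 0 fell, and 1 rose adjusted over the list alone (camera adjusted p = 0.931, upward, with a mean of 0.01 and a median of -0.04 that turned to 0.20 and 0.41 under median centring and spike scaling). Without mutant replicate 1, 3 rose and 4 fell. The plastid list was called under both scalings (adjusted p = 0.0362 and 0.00547), and its 27 photosystem and cytochrome genes were called under spike scaling (adjusted p = 0.0151). These calls used camera's preset correlation of 0.01, which makes their p-values too small. In the main fit the estimated correlations were 0.537 and 0.584, and camera's adjusted p with them was 0.982 for each list.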

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

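For the control signals every test was chosen only after the result was seen. Relative to the median of all probe sets, the mutant was 2.05-fold above wild type for the 25S rRNA control, and 1.62, 1.63, 1.70 and 1.60-fold above for the poly(A) controls DapX, LysX, PheX and ThrX, while the 5S rRNA control overlapped between genotypes (1.09-fold, exact permutation p = 0.8). More degraded RNA in the mutant would raise all 3' to 5' ratios, but their median log2 difference of 0.19 hid a rise for actin (0.30) and GAPDH (0.19) and a fall for ubiquitin (-0.22), so this could not be told. More poly(A) control added to the mutant, and nothing else, cannot account for the 25S rRNA difference of 1.03, because that RNA comes from the plant. Unequal addition together with a separate 25S rRNA difference was not tested and stayed open. A smaller share of mRNA in the mutant's total RNA could raise the poly(A) controls (log2 0.71) and 25S rRNA and stayed open. The 5S rRNA control did not show the separate rise this predicts, but its overlap came from mutant replicate 1 (ratio 0.60). Mutant replicates 2 and 3 had 1.26 and 1.05, against 0.79, 0.94 and 0.81 in wild type. The labels do not say when or whether the poly(A) controls were added. Scaling on them was not run. It would lower the mutant values relative to wild type, the opposite direction to scaling on the hybridisation spikes. The smaller rises were therefore not tested under it.

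For mutant replicate 1, the tests of its share of variance along the mutant effect and of shared handling were chosen only after the result was seen. Noise of a dim array was excluded, since its SD was 1.66 times that of the other mutant samples even among the brightest probe sets. A weaker effect of the same kind could be part of its place, with a slope of 0.832 on the other mutant samples against 0.939 and 0.984 for those. It was not the whole of it, because only 10.3% of the variance of its deviation lay along the mutant effect. Handling shared by the samples numbered 1 could also contribute, as their deviations correlated at 0.298, the highest of 9 pairs.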

How the results depend on the processing

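Against 3267 probe sets called, limma called 328 on the deposited signals, 1624 with arrays scaled on the hybridisation spikes, 2122 with a pseudocount of 1 and 5612 with array weights, which gave mutant replicate 1 a weight of 0.32. Leaving out a sample gave 1496 to 4107. Of these, 150 were higher on the deposited signals and 2682 with array weights, and 809 to 2076 with a sample left out. The number lower was 178 on the deposited signals, 318 with spike scaling, 1046 with a pseudocount of 1, 2930 with array weights and 687 to 2031 with a sample left out. At least 2-fold changes numbered 326 on the deposited signals, 525 without the 60% dimmest probe sets and 462 with a pseudocount of 64. Fewer probe sets and the larger added constant lower these last counts by construction. For the other values the cause was not tested.

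With the replicate number as a replicate block, limma called 3382 probe sets. Deviations from the group means correlated at 0.298, 0.009 and 0.150 between samples with the same number. Replicates 2 and 3 correlated more with another number (0.095 and 0.153), so the samples were taken to share only a number.

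Of 43 lists camera called 8. It called 4 on the deposited signals, 5 with the trimmed mean, 4 without the 40% dimmest probe sets, 5 to 8 with a sample left out and 0 with an estimated correlation (3 at an unadjusted threshold of 0.05). Fry, which tests a list against no change and not against the other genes, called 14 at its adjusted threshold. The adjusted p with an estimated correlation was 0.374 for expansins and xyloglucan enzymes, phenylpropanoid enzymes and tetrapyrrole synthesis. It was 0.525 for defensins and thionins, UDP-glycosyltransferases, elicitor and wound responsive genes and nuclear photosynthesis genes, and 0.546 for the expansin and xyloglucan enzyme families.

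Other settings ended the calls of 5 lists. For nuclear photosynthesis genes the adjusted p was 0.480 on the deposited signals, 0.412 with median centring, 0.206 with the trimmed mean and 0.703 with spike scaling. It was 0.0753 without the 40% and 0.0575 without the 60% dimmest probe sets, and 0.00889 to 0.0688 with a sample left out. For tetrapyrrole and chlorophyll synthesis it was 0.184 on the deposited signals, 0.123 with median centring, 0.0722 with the trimmed mean, 0.347 with spike scaling and 0.0625 without the 40% dimmest. For elicitor and wound responsive genes it was 0.0749 on the deposited signals, 0.0584 with the trimmed mean, 0.0625 without the 40% dimmest and 0.00889 to 0.0749 with a sample left out. For the expansin and xyloglucan enzyme families it was 0.0616 on the deposited signals, 0.0877 with spike scaling, 0.0674 with the replicate block and 0.0228 to 0.144 with a sample left out. For UDP-glycosyltransferase genes it was 0.0625 without the 40% dimmest.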

Other observations

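Several families had members that changed in lists that camera did not call. Of 21 beta-glucosidase genes 2 rose and 5 fell (camera adjusted p = 0.599, with a list median of 0.03 and a mean of -0.11), and fry, which tests against no change, called the list downward (adjusted p = 0.0112). BGLU46 and BGLU33 fell by 1.51 and 1.22 on the log2 scale, and BGLU25 rose 2.40-fold. Of 14 SWEET sugar transporter genes SWEET17 and SWEET16 fell, by 0.95 and 0.88 (limma), against 4 that fell without mutant replicate 1. Of 14 organelle RNA editing and splicing factors 2 rose and 3 fell, with OTP81 up by 1.68 and CRR21 down by 1.23. Of 11 RALF-like peptide genes RALFL32 and RALFL34 rose, by 1.21 and 0.78, against 4 that rose without mutant replicate 1. Auxin response and transport genes had a list median of -0.10, a mean of 0.02 and an upward camera test (adjusted p = 0.897), and WES1 and GH3.3 rose, by 0.59 and 0.52 (adjusted over the list alone 2 rose and 1 fell), against 1 that rose without mutant replicate 1.

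For adjacent genes no test was chosen only after the result was seen. Log2 differences of neighbours on a chromosome correlated at r = 0.065 over 5814 pairs (permutation p = 0.001, the smallest possible with 1000 permutations). Similar sequence of neighbours could contribute and stayed open: r was 0.063 without probe sets shared between genes, and similarity short of a shared probe set was not tested. For a place effect of the array or annotation, r between adjacent genes was lower, 0.018, for a difference between wild type replicates. That difference rests on fewer arrays, so noise may lower its r. It also cannot show a place effect that differs between the arrays of the genotypes, so a place effect was not excluded. At 2, 5, 20 and 100 genes apart r was 0.029, 0.037, 0.020 and 0.020 for the mutant effect and 0.020, 0.003, -0.009 and 0.004 between wild type replicates, so a place effect stayed open at 2 genes apart as well.

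For the splits of the samples no test was chosen only after the result was seen. The 6 samples form 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of them, the real one, had as many calls (3267, against at most 0), 1 had as many 2-fold calls (1015, against at most 0) and 1 had as many list calls (8, against at most 7). In every other split the mixed genotypes widen the spread within groups, so a limma count of 0 there tells little. Part of the genotype difference also stays in those contrasts, so their list calls are not a count of false calls.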
